A study of Rattus norvegicus with 6 samples.

How the data were processed

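Per the labels' protocols, total RNA of 6 thoracic aortas was depleted of ribosomal RNA, amplified by random priming along the whole transcript, labelled with Cy3 and hybridised by the Agilent one-colour method. The labels name 3 control and 3 peptide rats, each on 1 array, and the rats are taken as separate animals from the protocol. The growth protocol calls the rats female and the sample characteristics call them male, which was not settled here.

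The deposited scanner files hold spot intensity, made with Agilent Feature Extraction 11.0.1.1 and the protocol GE1_1100_Jul11, per the file headers. The processed intensity is background-subtracted and not normalised between arrays, per the file headers. The authors also deposited a value table on a log2 scale. Its columns have equal quartiles and a median of 6.3419 in all 6 arrays, so it was quantile normalised. Each column correlated best with its own array's scanner values (Pearson r across probes of at least 0.9974), which leaves its scale and direction known, and the step from spots to probes is not given in the sources used here.

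Control spots and spots marked as outliers were left out. The log2 processed signal of each array was lowered by the array's 75th percentile over non-control probes, and spots of a probe were averaged. The 37723 probes well above background on at least 3 of 6 arrays were tested, and 1081 were not. Peptide was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes, a threshold of 0.05 and no fold limit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

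Gene names came from the accessions of 50 catalogue probes, with 10 spots each. Of these, 30 matched the RefSeq gene table of the assembly GRCr8, which was used for names alone. The other 38774 probes are unnamed here. Probes with an NM or XM accession were counted as mRNA (33), those with LNC in the name or an XR accession as lncRNA (3857), and the rest as unclassified (34914). This class by probe name replaces the annotation that had been planned. Because no list had 5 measured members, list tests, their alternatives, and the alternatives on the probe chosen per gene were not run.

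The naming rule, fixed before the data were examined, takes mRNA genes past the threshold with groups that do not overlap. Places left are filled by the smallest unadjusted p, and up to 2 members are added from each list with none past the threshold. It named 4 genes: Cyp2e1, Enpp1, Ldha and Nlrp3. The 26 other genes were added after values were seen, as the complete set of matched genes. For lncRNA probes the rule allows 5 per direction, of which 2 per direction are printed.

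Slides were told apart by their scans. Alternatives fixed before the data were examined were other scalings, normexp background correction (offset 50), the deposited table, other filters on dim probes, the replicate number or the slide as a block, other variance models, other thresholds, and leaving out each array. The planned mean spot signal is not a column of these files, so normexp used the median spot and background signals. Slide 1 alone, the slide as a random block, and leaving out control 1 and peptide 1 together were added after seeing the data.

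The fit was tested on simulated arrays with the real probe means, 37723 probes and 200 of them changed. With variances drawn from the fitted prior, it found 0% of changes of 2-fold, 62.4% of 4-fold and 96.8% of 8-fold, and 4.3% of its calls were false. With the slide as a block it found 0%, 4.4% and 58.4%, and 3.6% of its calls were false. With the moderated spread of each probe taken as its true spread, the main fit found 90.4% of 4-fold and 100% of 8-fold changes, and the blocked fit 34% and 96%. False calls made up 9.2%, and 10.5% with the block. When slide effects with an SD of 0.7 were added to all probes of that simulation, the main fit found 66% and 94%, and the blocked fit 38.4% and 96%. False calls then made up 16.9%, and 9% with the block. The simulations drew noise independently for each probe. Its spread came from the fit without the slide, whose residuals already hold the slide gap within the peptide group. These shares therefore need not hold for the real arrays. No pair of arrays held identical values.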

Results

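RNA abundance was measured in the thoracic aorta of spontaneously hypertensive rats, an inbred strain that develops high blood pressure without treatment. Per the labels, 3 rats received an oligopeptide of the mushroom Ganoderma lingzhi intravenously at 5 mg/kg per day for 28 days, and 3 control rats received saline. The rats were 16 weeks old at collection. Each of the 6 samples was hybridised to its own one-colour array with 38804 different probes for mRNAs and long noncoding RNAs (lncRNAs). Between 95.41% and 95.85% of the probes lay well above background on the control arrays, and 96.96%, 98.04% and 97.86% on the peptide arrays 1, 2 and 3. No spot was saturated, and the small number of arrays limits the precision.

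The arrays came from 2 slides. All 3 controls and peptide 1 were on slide 1, and peptide 2 and 3 were on slide 2. The main counts, and the differences of the named genes, are therefore given over all arrays and with the slide as a block. The blocked value rests on peptide 1 against the 3 controls of its slide, so it describes a single treated rat.

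The question addressed by the design was which mRNAs and lncRNAs differ between the aortas of treated and control rats. Cyp2e1, a cytochrome P450 enzyme that oxidises ethanol and other small molecules, had the smallest unadjusted p of all probes. Its normalised log2 signal was -3.1 ± 0.32 (SD, n = 3) in the controls and -1.06 ± 0.56 (SD, n = 3) in the peptide group, a difference of 2.04 (SE 0.35) or 4.1-fold. All 3 peptide arrays lay above all 3 controls. Enpp1, an ectoenzyme that makes pyrophosphate, an inhibitor of calcification, was at 2.2 ± 0.65 in the controls and 1.43 ± 0.1 in the peptide group (SD, n = 3 each). All 3 peptide arrays lay below all 3 controls, with a difference of -0.77 (SE 0.35), or -0.39 without control 1, the highest of the controls.

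Neither gene passed the test. For Cyp2e1 the limma p was 0.000124, and the Benjamini-Hochberg adjusted p was 0.757. For Enpp1 these were 0.0512 and 0.757. The unadjusted limma p of Enpp1 depended on the scaling, at 0.0138 after quantile normalization and 0.228 after median scaling. With the slide as a block the Cyp2e1 difference was 2.46 (SE 0.43), and that of Enpp1 was -0.82 (SE 0.49), with a limma adjusted p of 1 for both. The processed signal of Cyp2e1 was dim, at 25.1, 33.9 and 25.5 on the control arrays and 152, 186 and 102 on the peptide arrays, and after a normexp background correction that adds 50 to each signal its difference was 0.46 with the 75th percentile and 1.02 with quantile normalization.

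**Figure D1:**
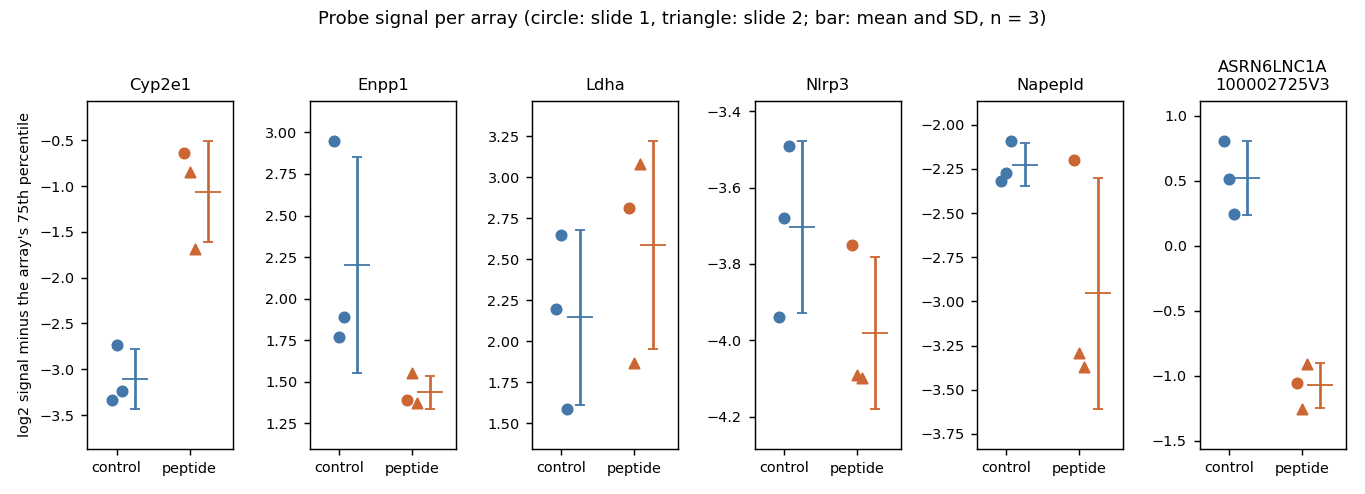
Normalised log2 signal (vertical axis, relative to each array's 75th percentile) of 6 probes on the control (blue) and peptide (orange) arrays, with circles for slide 1, triangles for slide 2, and bars for the mean and SD of 3 arrays. The Cyp2e1 groups do not overlap (-3.1 and -1.06 on average), while Napepld was lower on the 2 slide 2 arrays and not on peptide 1.

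Of the 35 gene lists fixed before the data were examined, 33 had no member with a named probe and none had 5, so no list was tested. The other 2 lists had 1 member each. Ldha, the lactate dehydrogenase subunit of the glycolysis and hypoxia list, had a log2 difference of 0.44 (SE 0.39, limma adjusted p = 0.758), and 0.67 (SE 0.57) with the slide as a block. Nlrp3, an inflammasome sensor in the cytokine and adhesion list, had a difference of -0.28 (SE 0.28, limma adjusted p = 0.769) and of -0.05 (SE 0.31) with the block, and its sign turned after quantile normalization (0.06). The sexes given in the labels differ between fields, and no named probe measured a Y-linked gene or Xist, so the sex was not checked here.

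Only 30 probes could be matched to a gene name, 29 of protein-coding genes and 1 of a lncRNA gene. All 30 are given, so that none was picked by its value. Of these genes, in the main analysis 1 had an unadjusted p under 0.05 (Cyp2e1), 7 had a difference above 0 and 23 below it. The median of all tested probes was itself -0.214. Relative to that median 18 genes were lower and 12 higher, and after quantile normalization 19 were below 0 and 11 above.

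The genes with the next lowest differences after Enpp1 were Napepld, which makes N-acylethanolamines (-0.72, SE 0.35), the luteinizing hormone receptor Lhcgr (-0.69, SE 0.39) and the neurotrophic factor Gdnf (-0.64, SE 0.37). These differences lay in peptide 2 and 3, at -1.1, -1.04 and -1.07 from the controls. Peptide 1, on the slide of the controls, was at 0.02, 0.01 and 0.2. The same held for the scaffold protein Dlg4 (-0.78 against 0.01), the ATP-gated channel P2rx2 (-0.8 against 0.19), the pyruvate dehydrogenase kinase Pdk3 (-0.58 against 0.14), the nuclear export factor Cse1l (-0.58 against 0.11) and the lncRNA gene LOC108352165 (-0.68 against 0.36). The sizes depended on the scaling and background correction. Over these alternatives and the deposited table, the difference over all arrays ran from -0.84 to -0.17 for Napepld and -0.94 to -0.09 for Lhcgr. For Gdnf it ran from -0.78 to -0.11, for Dlg4 from -0.75 to -0.14 and for P2rx2 from -0.83 to -0.03. For Pdk3 it ran from -0.67 to -0.02, for Cse1l from -0.36 to -0.04 and for LOC108352165 from -0.58 to -0.01.

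Fibroblast growth factor Fgf2 was at -0.67 in peptide 2 and 3 and at 0.71 in peptide 1. N-cadherin (Cdh2) was at -0.81 and 0.79, and the phospholipase Pld1 at -0.69 and 1.02. Values on opposite sides of 0 were also found for Med16 (-0.16 and 0.22), Ppp2r2b (-0.17 and 0.13), Ndfip1 (-0.22 and 0.17), Eif4b (-0.21 and 0.64), Trim2 (-0.15 and 1) and the nucleoside transporter Slc28a2 (0.3 and -0.48).

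Besides Cyp2e1, Enpp1, Ldha and Nlrp3, differences on the same side of 0 on both slides were found for Pdcd10 (-0.84 in peptide 2 and 3 and -0.08 in peptide 1), the exon junction protein Magoh (-0.67 and -0.08), Pop7 (-0.57 and -0.16), the microtubule-associated protein Map2 (-0.52 and -0.16), the kinase Ptk2b (-0.44 and -0.04), Odf2l (-0.38 and -0.19) and Ndfip2 (-0.29 and -0.15). Mex3c (0.26 and 0.34) and the N-acetyltransferase Nat1 (0.03 and 0.6) were above 0 on both, although Mex3c turned to -0.46 with normexp and the 75th percentile. None of these had an unadjusted p under 0.05.

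**Figure D2:**
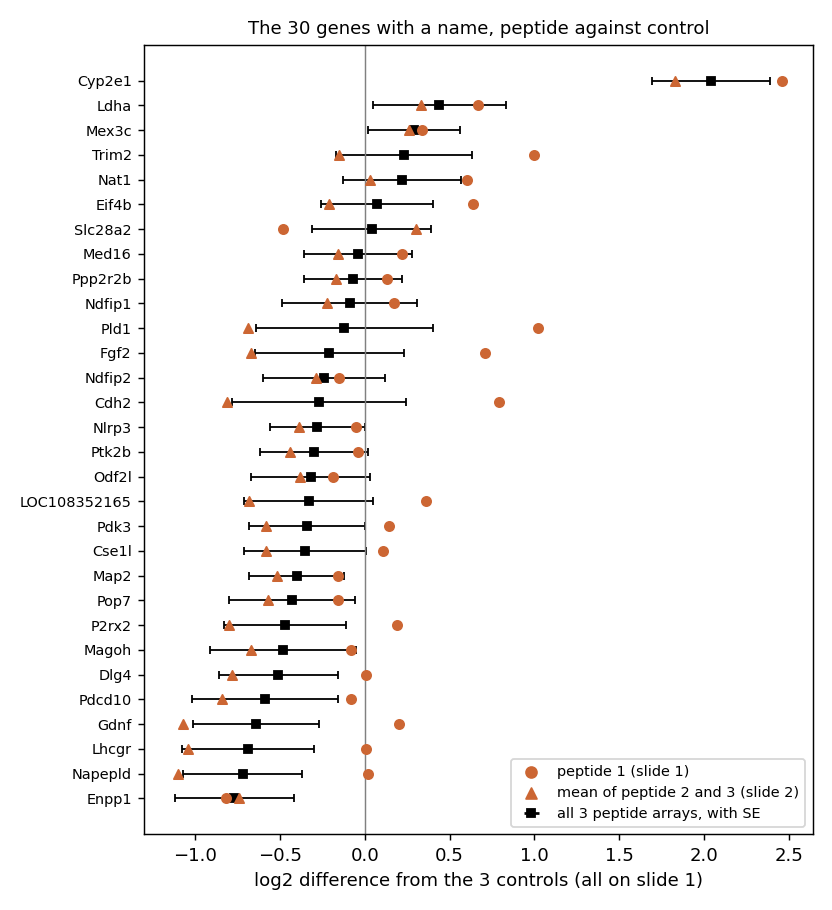
Log2 difference from the 3 controls (horizontal axis) for the 30 genes with a name, with black squares and SE bars for all 3 peptide arrays, circles for peptide 1 on the slide of the controls, and triangles for the mean of peptide 2 and 3 on the other slide. Cyp2e1 lies at 2.04, apart from the other genes, and for many genes the circle and the triangle lie on opposite sides of 0.

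Probes were classed as lncRNA by an LNC name or an XR accession, and the 34914 unclassified probes may hold others. Among the 3675 tested probes of this class, 0 passed the threshold with limma (smallest adjusted p = 0.757). At an unadjusted p under 0.05 there were 142, of which 23 were higher and 119 lower in the peptide group. Every array moved that count: it was 576, 94 and 59 without control 1, 2 and 3, and 1193, 34 and 29 without peptide 1, 2 and 3. With a 2-fold limit as well, 9 were higher and 34 lower. The excess of lower probes depended on single arrays and on the scaling. Without control 2 there were 37 higher and 57 lower, or 32 and 39 with the 2-fold limit, and without control 3 there were 23 and 36, or 20 and 26. Leaving out control 1 gave 18 and 558, or 4 and 116, and leaving out peptide 1 gave 134 and 1059, or 59 and 320. Without peptide 1 each group lies on its own slide, so slide and peptide cannot be told apart in those counts. Without peptide 2 there were 12 and 22, or 9 and 18, and without peptide 3 there were 9 and 20, or 7 and 13. After quantile normalization 79 were higher and 113 lower, or 13 and 8 with the 2-fold limit, and after median scaling 54 and 110, or 14 and 7. Normexp with the 75th percentile enlarged it to 8 and 894, or 3 and 43. The median difference of the class moved from -0.276 to -0.032, -0.073 and -0.675. With the slide as a block 0 passed, and 13 were higher and 33 lower at an unadjusted p under 0.05, or 4 and 23 with the 2-fold limit. Probes of this class carry no gene name here, and 4 are given by their identifiers. ASRN6LNC1A100002725V3 was at 0.52 ± 0.28 (SD, n = 3) in the controls and -1.07 ± 0.17 (SD, n = 3) in the peptide group, 3.02-fold lower. Its difference was -1.59 (SE 0.28, limma adjusted p = 0.757) and -1.58 with the slide as a block. ASRN6LNC1A100000289V3 was well above background on 3 control arrays and on 1 of 3 peptide arrays. The size of its difference is therefore not settled, at -2.19 in the main analysis, -0.66 with the block, -1.15 in the deposited table, -0.25 with normexp and quantile normalization and -2.96 without peptide 1. ASRN6LNC1A100111761V3 had a difference of 1.33 (SE 0.41) and of 0.72 with the block, and neither passed the test. ASRN6LNC1A100002620V3 was well above background on 3 peptide arrays and on 0 control arrays, and no fold is given for it.

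Over all 37723 probes tested, limma found 0 past the adjusted threshold, and 0 with the slide as a block. At an unadjusted p under 0.05 there were 1068 probes (2.83%), 202 higher and 866 lower, and 632 with the block, 257 higher and 375 lower. Without control 1 and 3 there were 3640 and 701, and without peptide 1, 2 and 3 there were 9149, 467 and 238. Leaving out control 2 gave 558 higher and 638 lower. After quantile normalization 690 were higher and 778 lower, after median scaling 603 and 598, and after normexp with the 75th percentile 152 and 5756. In 482 probes all 3 peptide arrays lay above all controls and in 1580 below, together 5.47% where chance gives 10%. At least a 2-fold difference with an unadjusted p under 0.05 was found for 103 higher and 237 lower probes. The split depended on single arrays. Without control 1, 2 and 3 there were 61 higher and 709 lower, 515 and 489, and 198 and 321. Without peptide 1, 2 and 3 there were 654 and 2161, 130 and 221, and 45 and 116. In the counts without peptide 1 each group lies on its own slide, so slide and peptide cannot be told apart. It also depended on the scaling, with 105 higher and 55 lower after quantile normalization and 126 and 44 after median scaling. The excess of lower probes stayed with the slide as a block (113 and 271) and with normexp and the 75th percentile (100 and 243). Of the 33 probes with an mRNA accession, 0 passed over all probes and 1 (Cyp2e1) when adjusted within that class (adjusted p = 0.0041). That adjustment covers these 33 probes alone, and mRNA probes among the 34914 unclassified ones are not in it. With normexp and the 75th percentile the unadjusted limma p of Cyp2e1 was 0.282, where the median difference of all probes was -0.494. With normexp and quantile normalization that p was 0.000782. In both settings 0 probes passed the adjusted threshold.

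Pairs of arrays on different slides differed more on average than pairs on a slide, whichever group they came from. The root mean square log2 difference averaged 0.593 for pairs of the same group and slide and 0.516 for different groups on a slide. It averaged 0.765 for the same group and 0.756 for different groups on different slides. Single pairs overlapped, with 0.789 for control 1 and 3 on a slide and 0.623 for control 2 and peptide 3 across slides. After quantile normalization control 2 lay nearer to peptide 2 and 3 (0.525 and 0.489) than to control 1 (0.683). Leaving out control 1 and peptide 1 together, a choice made after seeing the data that leaves 1 group per slide, gave 14449 probes past the threshold, 1778 higher and 12671 lower, and in that comparison the slide and the peptide cannot be told apart.

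**Figure D3:**
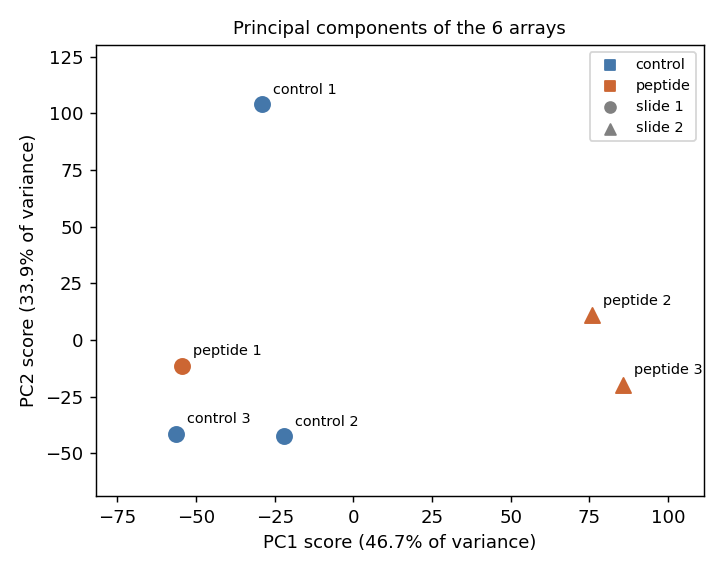
Scores of the 6 arrays on the first (horizontal, 46.7% of the variance) and second (vertical, 33.9%) principal component of the normalised log2 signal, coloured by group, with circles for slide 1 and triangles for slide 2. Peptide 2 and 3 lie at 76.02 and 85.8 on the first component, peptide 1 at -54.44 among the controls, and control 1 stands apart on the second at 103.93.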

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

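The slide 1 fit, the random slide block and the joint omission of control 1 and peptide 1 were chosen after seeing the data. The count of probes past the adjusted threshold was 0 under every alternative fit except 3. Array weights gave 23340 probes (16 mRNA, 2715 lncRNA), but their estimation stopped before it converged and put a weight of 47.94 on control 2 against 0.11 on control 1 and peptide 1. Leaving out control 1 and peptide 1 together gave 14449 (8 mRNA, 1895 lncRNA). Leaving out 1 array gave 0 to 4, with the 4 found without control 2. Other thresholds gave 1068 probes at an unadjusted p under 0.05 (1 mRNA, 142 lncRNA) and 340 with a 2-fold limit (1 mRNA, 43 lncRNA), and adjusting within the class gave 1 mRNA. The 2-fold count ran from 27 with normexp and quantile normalization to 4970 without control 1 and peptide 1, with 3297 under array weights, 131 with a random slide block, 160 after quantile normalization, 170 after median scaling and 158 in the deposited table. Leaving out 1 array gave 770, 1004 and 519 without control 1, 2 and 3, and 2815 and 161 without peptide 1 and 3. The count without peptide 1 sets slide 1 against slide 2, so slide and peptide cannot be told apart in it. Normexp used an offset of 50, which compresses dim probes. Other causes were not tested.

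Same-numbered control and peptide arrays deviated from their group means with correlations of -0.013, -0.19 and -0.236, and no array correlated best with its own number. The values thus show no pairing by number, but so few arrays cannot exclude a pairing by design. The fit with the replicate block gave 0 probes, 0 mRNA probes and 0 lncRNA probes.

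Of the 30 named genes, 8 kept their sign under all 21 alternatives and 22 did not, and the cause was not tested. The 21 are not separate checks. Other filters on dim probes, the replicate block and the trend and robust variance leave these differences as in the main fit. The slide as a block and slide 1 alone give the same differences. The 8 were Cyp2e1 (0.46 to 2.46), Enpp1 (-0.98 to -0.37), Ldha (0.17 to 0.8), Nat1 (0.02 to 0.6), Pop7 (-0.66 to -0.03), Ptk2b (-0.45 to -0.02), Pdcd10 (-0.89 to -0.08) and Map2 (-0.73 to -0.06). The last 5 came close to 0, so a kept sign says little about them. With the slide as a block, and equally in slide 1 alone, 15 turned: Cdh2 0.79, Napepld 0.02, Gdnf 0.2, Lhcgr 0.01, LOC108352165 0.36, Cse1l 0.11, Ndfip1 0.17, P2rx2 0.19, Ppp2r2b 0.13, Pdk3 0.14, Slc28a2 -0.48, Dlg4 0.01, Med16 0.22, Fgf2 0.71 and Pld1 1.02. A random slide block turned Cdh2 (0.21), Ndfip1 (0.03), Ppp2r2b (0.02), Slc28a2 (-0.19), Med16 (0.08), Fgf2 (0.21) and Pld1 (0.39). Quantile normalization turned Ndfip1 (0), Nlrp3 (0.06), Ppp2r2b (0.24) and Pld1 (0.06), and the deposited table Ndfip1 (0), Nlrp3 (0.05), Ppp2r2b (0.22), Med16 (0) and Pld1 (0.05). Median scaling turned Ndfip1 (0.12), Ppp2r2b (0.13), Med16 (0.17) and Pld1 (0.08). Normexp with the 75th percentile turned Mex3c (-0.46), Ndfip1 (0.19), Ndfip2 (0.04) and ASRN6LNC1A100002620V3 (-0.76, no measured difference, as no control array held it well above background), and with quantile normalization Nlrp3 (0.02), Ppp2r2b (0.07) and Pld1 (0.07). Array weights turned Ndfip1 (0.32) and Ndfip2 (0.09), and leaving out control 1 and peptide 1 turned Eif4b (-0.06), Ndfip1 (0.26) and Ndfip2 (0.11).

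Leaving out 1 array turned 12 genes, whose differences then ranged from -0.81 to 0.13 for Cdh2, -0.76 to 0.04 for Magoh, -0.33 to 0.39 for Ndfip1, -0.17 to 0.09 for Ppp2r2b, -0.54 to 0.03 for Odf2l, -0.47 to 0.15 for Ndfip2, -0.69 to 0.3 for Pld1, -0.2 to 0.3 for Slc28a2, -0.67 to 0.16 for Fgf2, -0.15 to 0.62 for Trim2, -0.21 to 0.29 for Eif4b and -0.29 to 0.12 for Med16.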

Other observations

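All tests in this part were chosen after the result was seen, except the one on intensity for control 1 and the correlation of opposite strands. Probes named after ultraconserved elements, stretches shared between distant mammals, covered 479 elements on both strands. Both strands were well above background on all 6 arrays for 290 elements, the plus strand alone for 83, the minus strand alone for 70 and neither for 36. The same call held for 373 of 479 plus and 360 of 480 minus probes, and for 36399 of all 38804 probes. Whether both strands were called together more often than these shares give was not tested. One hypothesis was that the strands of an element would change together. Across 381 elements the log2 differences of the strands had a Pearson r of -0.001 (permutation p = 0.989, adjusted p = 0.989) and a Spearman rho of 0.005 (permutation p = 0.917, adjusted p = 0.989), and neither differed from 0 by these tests. Both strands had the same sign in 61.7% of elements, where the shares below 0 of the plus (80.3%) and minus strand (74%) alone give 64.6% (permutation p = 0.143, adjusted p = 0.428). Elements are not independent replicates.

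Peptide 2 and 3 stood apart from the 4 arrays of slide 1. On 45 scanner control probes, with their common shift taken out, both slide 2 arrays lay outside the range of the 4 others for 57.8%, where chance gives 13.3% and the highest of the other pairs of arrays reached 31.1%. A difference of slide, scan or labelling could give this, although such probes may also bind sample RNA. A response shared by the treated rats stays open. On the line from the mean of the 3 controls (0) to peptide 2 and 3 (1), peptide 1 lay at -0.04. Each control was instead placed on a line that started from the 2 other controls, and lay between 0.04 and 0.42. Those lines differ from that of peptide 1, so the values cannot be set against each other. Moreover, 1 array excludes nothing about the other rats.

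Cyp2e1 was higher on every peptide array. Its lowest spot there lay 0.7 log2 units above its highest spot on any control array, and peptide 1 lay 2.46 above the controls of its own slide. The gene was picked from these values, so the gap is no test of noise of single spots. As for peptide 1, a slide cannot separate arrays that lie on it, so its value is no test of the slide either. For peptide 2 and 3, at 1.83, slide and peptide cannot be told apart, since no control was on slide 2. A smallest p as low was found in 5 of the 10 splits of the arrays into 3 and 3, the real one included, the lowest being 1.543e-05. Among them was control 1 with peptide 2 and 3 against the rest, which gave 7692 probes past the adjusted threshold. The splits are therefore no pure measure of chance. A response to the peptide stays a hypothesis, and chance among many probes is not excluded.

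Control 1 stood apart from the other controls by a root mean square log2 difference of 0.758. With a smooth trend on intensity taken out it was still 0.688, against at most 0.387 for control 2, control 3 and peptide 1, which argues against intensity alone as the cause. No biological explanation was tested.

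The 10 splits of the 6 arrays are too few for a share under 0.05, and counts of splits as large include the real one. For probes past the adjusted threshold the real split gave 0, and all 10 splits gave at least as many. The highest other was 7692, for control 1 with peptide 2 and 3 against the rest. That split gave 0 after quantile normalization, but 7219 probes at an unadjusted p under 0.05, the most of the 10 splits (1468 for the real one). The log2 distance from median to 75th percentile was 1.83, 1.95 and 1.916 on these 3 arrays and 1.44 to 1.554 on the others, and the cause was not tested. For probes at an unadjusted p under 0.05 and 2-fold the real split gave 340 and the highest other 2099, with 5 splits as large, and for lncRNA probes 43 and 288, with 4 as large. Adjusted within the class, mRNA probes gave 1 and at most 3, with 3 splits as large. Probes well above background on all arrays of a group and on none of the other numbered 110, of which 109 were found in the peptide group. The highest other split had 103, with 1 split as large. That other split was again control 1 with peptide 2 and 3 against the rest. Peptide 2 and 3, on slide 2, had the highest shares of probes well above background (98.04% and 97.86%). The 110 can therefore not be credited to the peptide rather than the slide.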
